A study of Homo sapiens with 12 samples.

How the data were processed

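RNA sequencing libraries of 2 T-ALL cell lines were used, Jurkat and Molt-4, each without and with chidamide, as 4 groups of 3 libraries. The libraries carry the letters J and M, which were read as Jurkat and Molt-4, the only lines that the growth protocol names. The identity of the cultures was not verified. The treatment protocol gives 2 µM for 48 h, while the labels of the treated libraries carry 48, 49 and 50 h for replicates 1, 2 and 3, so time and replicate number cannot be separated there.

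The deposited values are FPKM per gene, made by the authors before deposit. Per the submitters' processing notes, the authors used STAR, HTSeq and DESeq2 with the genome build hg19. The notes give no versions, and they state neither the order of the steps nor how FPKM was obtained from them. The table held 25146 genes by symbol, of which 20104 were above 0 in at least 1 library, with values rounded to 2 decimals. All columns with values per sample were used. Of the gene names, 23122 matched a RefSeq symbol of the GRCh38 annotation and 1124 more an older symbol, and no coordinates were taken from that build.

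FPKM values hold no read counts, so the depth of the libraries is unknown and no counting interval can be given. It was checked whether low values are whole multiples of what 1 read is worth. Of 3175 values 47.5% lay within 0.15 of a whole multiple with steps estimated from the data, against 33.4% with equal steps for every library and 28.1% to 38.9% with 10 draws of random steps. Whole reads were therefore not recovered. The estimated worth of 1 read relative to untreated Jurkat replicate 1 lay between 0.874 and 1.29.

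Genes with an FPKM of at least 1 in at least 3 of the 12 libraries were kept, which left 13840. Their values were log-transformed as log2(FPKM + 1), and a fold change on this scale understates the change of genes with low values. A linear model with 1 mean per group was fitted to all 12 libraries with limma (lmFit and eBayes with an intensity trend, 8 residual degrees of freedom). The 4 comparisons were treated against untreated in each line, the difference of these responses (Molt-4 minus Jurkat) and untreated Molt-4 against untreated Jurkat. P-values were two-sided, adjusted by the Benjamini-Hochberg method over the genes of each comparison, and called at an adjusted p under 0.05.

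Of 36 gene lists fixed before the data were examined, 34 were tested with camera in limma, with a preset inter-gene correlation of 0.01 and adjustment over the 34 lists of each comparison. The mitochondrially encoded genes and the T-cell receptor variable genes of the Jurkat clone have no member in the table and were not analysed here. Camera with the correlation estimated from the data served as an alternative. For each list the called members were also counted with the adjustment made over the list alone. The overlap of the calls in both lines was set beside that of independent lists.

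The genes named were chosen by a rule set before the data were examined. NOTCH1, MYC, NOTCH3, HES1, HES4, HEY1, DTX1, NRARP, PTCRA, IL7R, HDAC1, HDAC2, HDAC3, HDAC10 and CDKN1A were named in each treatment comparison. For each line the rule added the 6 largest rises and 6 largest falls among called genes with a mean FPKM of at least 5 in the higher group and no overlap between treated and untreated libraries, a separation that chance gives 10% of genes with 3 against 3. It also added the 5 highest and 5 lowest genes called in both lines by the smaller change, the 4 highest and 4 lowest of the difference (with a mean FPKM of at least 5 in a group) and the 5 highest and 5 lowest between untreated lines. For each list it allowed up to 4 called members with the largest change, or the 2 highest-expressed where none was called. Pseudogenes, features without a symbol, Y-linked genes and XIST were skipped.

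The alternatives set before the data were examined were a pseudocount of 0.1, no filter on low values, an FPKM of at least 5 in 3 libraries, median-of-ratios scaling, quantile normalization, a fit of only the groups compared, robust empirical Bayes, the replicate number as a block, an added requirement of a 2-fold change, the estimated correlation for the lists, and each of the 12 libraries left out in turn. Where a library was left out, the other groups helped to estimate the spread. FPKM rescaled to a total of 1000000 per library without the 2 7SL RNA genes was chosen after seeing the data. The model was tested on simulated data with 200 changed genes in the Jurkat comparison. It recovered 40 of 40 genes at a log2 change of -2, 37 and 38 of 40 at -1 and 1, and 25 and 22 of 40 at -0.5 and 0.5, and called 8 of 13640 unchanged genes.

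The test of a lower depth of untreated Jurkat replicate 3 is the third that was tried, with bounds set after seeing the data. The 2 earlier ones compared the worth of 1 read with other replicates (0.965 times the mean), with the same verdict, and were given up since whole reads were not recovered. Deeper sequencing of treated libraries was first excluded by the worth of 1 read, a test then found void and replaced by that of libraries left out. Void rules added after the values were seen turned the verdicts on splits of the difference and of both lines from excluded to undecided.

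Computations used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.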

Results

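RNA of 2 human T-cell acute lymphoblastic leukaemia (T-ALL) lines, Jurkat and Molt-4, was sequenced after culture with or without chidamide, as 4 groups of 3 libraries. Chidamide (tucidinostat) is a benzamide that inhibits the histone deacetylases HDAC1, HDAC2, HDAC3 and HDAC10. The protocol gives 2 µM for 48 h, while treated libraries are labelled 48, 49 and 50 h in step with replicate number. The series is about NOTCH1, a receptor gene often mutated in T-ALL, and MYC, one of its direct targets. Values were FPKM without read counts, so the depth is unknown. Total FPKM per library lay between 698435 and 869059, and between 11643 and 13228 genes reached an FPKM of 1. The 7SL RNA genes held 10.1% of the total FPKM in untreated Molt-4 replicate 3, against 2.25% to 5.35% in the other libraries. Libraries of 1 group correlated across genes with r between 0.989 and 0.995 on log2(FPKM + 1) values. No pair within a group had more than 0.349% identical values among genes expressed in both. Untreated Jurkat replicate 3 stood apart from its group: the SD of its log2 ratios to the other untreated Jurkat libraries was 0.371 and 0.378, against 0.248 to 0.280 for the other pairs within a group. Levels are given as mean FPKM ± SD over 3 libraries. Log2 changes are differences of log2(FPKM + 1) ± SE, which understate the change of genes with low values. Genes and lists with an adjusted p under 0.05 are referred to as called. The number of called list members adjusted over the list alone is given where it differs from that among all genes tested. Ranges of adjusted p are over all alternatives of the processing. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values measure only the spread between these samples.

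The first comparison asked what changed with chidamide in Jurkat. The cyclin-dependent kinase inhibitor gene CDKN1A (p21) rose from 1.29 ± 0.327 to 50.8 ± 1.08 FPKM (log2 change 4.51 ± 0.11, adjusted p = 4.07e-11). The surrogate light chain gene IGLL1 went from 341 ± 23.5 to 5.91 ± 1.2 FPKM (log2 change -5.64 ± 0.11, adjusted p = 1.31e-11). DNTT, which encodes terminal deoxynucleotidyl transferase, fell from 123 ± 39.1 to 3.87 ± 0.74 FPKM (log2 change -4.64 ± 0.18, adjusted p = 1.83e-09), and the recombinase gene RAG1 from 37.4 ± 0.806 to 4.79 ± 0.221 FPKM (log2 change -2.73 ± 0.068, adjusted p = 4.8e-11). As groups, genes of DNA replication and DNA repair fell, while neuronal and MHC class II genes rose. Genes activated by MYC in ribosome biogenesis and growth also fell (camera adjusted p = 1.69e-14, and adjusted p = 0.202 with an estimated correlation).

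NOTCH1 fell in Jurkat from 20.8 ± 2.72 to 14 ± 0.595 FPKM (log2 change -0.53 ± 0.087, adjusted p = 0.000264). MYC fell from 259.7 ± 34.2 to 164 ± 2.48 FPKM (log2 change -0.65 ± 0.079, adjusted p = 2.11e-05). Among the genes that NOTCH1 activates in T-ALL, PTCRA, the pre-T-cell receptor alpha chain gene, fell from 5.84 ± 1.25 to 0.0467 ± 0.0404 FPKM (adjusted p = 1.32e-08). DTX1 fell from 42.1 ± 8.97 to 24.1 ± 1.3 FPKM (adjusted p = 0.000563). HES4 fell from 113 ± 4.92 to 83.3 ± 5.98 FPKM (adjusted p = 0.0061). BCAT1 and SKP2 fell by 1.82 ± 0.13 and 1.14 ± 0.082 on the log2 scale (adjusted p between 2.3e-07 and 2.91e-07). Other targets rose. HEY1 went from 0.643 ± 0.124 to 6.66 ± 1.8 FPKM, NRARP from 0.433 ± 0.107 to 2.09 ± 0.235 FPKM and TRIB2 from 16.3 ± 1.68 to 34.3 ± 2.73 FPKM (adjusted p between 1.11e-06 and 1.33e-05). HES1 was low and rose from 1.03 ± 0.28 to 1.62 ± 0.469 FPKM (adjusted p = 0.0353). This call was lost without untreated Jurkat replicate 2 or 3 or treated Jurkat replicate 2 or 3 (adjusted p = 0.107, 0.0961, 0.134 and 0.123, range 0.0025 to 0.338). It was also lost with no filter on low values and within the 2 groups alone, and the log2 change of HES1 turned to -0.17 under quantile normalization. NOTCH3 was at 27.1 ± 2.45 FPKM untreated and 27.1 ± 0.409 FPKM treated (adjusted p = 1.0). IL7R was at 6.26 ± 0.517 FPKM untreated and 6.99 ± 0.536 FPKM treated (adjusted p = 0.512). Of the NOTCH1 targets tested, 9 of 22 were higher and 7 lower (camera adjusted p = 0.897). Their median log2 change was 0.16, and -0.14 under quantile normalization. Of the genes of the NOTCH pathway itself, 14 of 33 were higher and 7 lower (camera adjusted p = 0.235). Members that rose were the receptor-cleaving protease gene ADAM10, from 103 ± 3.31 to 555 ± 15.2 FPKM, and the coactivator gene MAML3, from 0.247 ± 0.133 to 2.89 ± 0.159 FPKM (adjusted p between 3.2e-11 and 4.09e-08).

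Of the genes activated by MYC in ribosome biogenesis and growth, 1 of 52 were higher and 47 lower (1 and 48 adjusted over the list alone) (camera adjusted p = 1.69e-14, and adjusted p = 0.202 with an estimated correlation). Their median log2 change was -0.77. The telomerase gene TERT fell from 13.2 ± 1.72 to 1.02 ± 0.406 FPKM. LYAR fell from 88.5 ± 17.4 to 35.2 ± 0.535 FPKM. SRM, the spermidine synthase gene, fell from 154 ± 26.9 to 63.7 ± 2.9 FPKM. The adjusted p of these genes lay between 7.72e-08 and 1.12e-06. The member that rose was the cyclin gene CCND2, from 3.62 ± 0.335 to 6.36 ± 0.622 FPKM (adjusted p = 7.27e-05). Of the cytosolic ribosomal protein genes, 4 of 64 were higher and 32 lower (4 and 33 adjusted over the list alone) (camera adjusted p = 3.22e-05, and adjusted p = 0.433 with an estimated correlation). Their median was -0.16, and the call of the list was lost under quantile normalization (adjusted p = 0.151 with it, range 4.65e-07 to 0.433). RPS23 fell from 3172 ± 85.3 to 1772 ± 43.5 FPKM and RPL21 from 1216 ± 35.2 to 827 ± 10.2 FPKM.

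Of the genes of DNA replication and the G1/S transition, 1 of 39 were higher and 30 lower (1 and 31 adjusted over the list alone) (camera adjusted p = 3.48e-08, and adjusted p = 0.00341 with an estimated correlation). Their median log2 change was -0.32. The replicative polymerase gene POLE fell by 0.84 ± 0.077, the helicase component gene CDC45 by 0.73 ± 0.066 and the thymidylate synthase gene TYMS by 0.70 ± 0.037 on the log2 scale (adjusted p between 2.14e-08 and 2.19e-06). Of the homologous recombination and repair genes, 0 of 32 were higher and 22 lower (camera adjusted p = 1.35e-05, and adjusted p = 0.0249 with an estimated correlation). RAD54L fell from 48 ± 5.74 to 25.1 ± 1.41 FPKM. Mitotic genes went both ways, 12 of 40 higher and 6 lower (camera adjusted p = 0.907). Their median was 0.0085 and mean -0.0055. UBE2C fell from 129 ± 7.95 to 80.2 ± 4.89 FPKM and TOP2A rose from 108 ± 7.64 to 158 ± 3.31 FPKM. Of the CDK inhibitor genes, 4 of 6 were higher and 0 lower (camera adjusted p = 0.0461, and adjusted p = 0.177 with an estimated correlation). Besides CDKN1A, CDKN2D rose from 23.5 ± 4.51 to 63.3 ± 2.87 FPKM. The call of this list was lost without untreated Molt-4 replicate 2 (adjusted p = 0.0531, range 0.0115 to 0.177), with no filter (0.094) and within the 2 Jurkat groups alone (0.05004).

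Of the pro-apoptotic genes, 13 of 23 were higher and 2 lower (camera adjusted p = 0.0782). For this list the adjusted p was 0.0358 with FPKM of at least 5 in 3 libraries and 0.0151 under quantile normalization (range 0.0151 to 0.177). BMF rose from 4.21 ± 0.954 to 15.4 ± 3.02 FPKM, and the death receptor gene TNFRSF10B from 18.6 ± 2.58 to 41.7 ± 3.4 FPKM. Of the anti-apoptotic genes, 5 of 10 were higher and 2 lower (5 and 3 adjusted over the list alone) (camera adjusted p = 0.416). BCL2L1 fell from 53.9 ± 1.47 to 35.9 ± 1.88 FPKM (adjusted p = 2.29e-06). Of the p53 target genes, 11 of 23 were higher and 3 lower (camera adjusted p = 0.0834). The p53 list reached an adjusted p of 0.0327 with FPKM of at least 5 in 3 libraries (range 0.0327 to 0.243). GADD45A rose from 15.2 ± 0.195 to 38.8 ± 2.42 FPKM.

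Neuronal genes rose in Jurkat, and not all of them were silent before treatment, as the level of TUBB3 below shows. Of the neuronal genes, 31 of 35 were higher and 1 lower (31 and 2 adjusted over the list alone) (camera adjusted p = 2.69e-10, and adjusted p = 0.00177 with an estimated correlation). Their median log2 change was 1.12. The tubulin gene TUBB3 rose from 9.53 ± 2.56 to 81.4 ± 3.54 FPKM, the secretogranin gene SCG2 from 0.0533 ± 0.0153 to 10.4 ± 0.156 FPKM and the adhesion molecule gene L1CAM from 0.080 ± 0.0436 to 13.9 ± 1.42 FPKM (adjusted p between 6.72e-11 and 8.1e-09). Of the MHC class II presentation genes, 9 of 10 were higher and 0 lower (camera adjusted p = 0.00011, and adjusted p = 0.0298 with an estimated correlation). HLA-DRA rose from 0.020 ± 0.0346 to 4.88 ± 0.976 FPKM, and HLA-DPB1 from 0.163 ± 0.182 to 3.13 ± 0.545 FPKM. Of the MHC class I presentation genes, 9 of 15 were higher and 3 lower (camera adjusted p = 0.056). HLA-B rose from 49.8 ± 9.19 to 286 ± 37.4 FPKM, and HLA-F from 4.92 ± 0.231 to 33.9 ± 2.1 FPKM. The MHC class I list reached an adjusted p of 0.0401 without untreated Jurkat replicate 1, 0.0451 without treated Jurkat replicate 1, 0.0477 without treated Jurkat replicate 2, 0.0459 without untreated Molt-4 replicate 3 and 0.0495 without treated Molt-4 replicate 2 (range 0.00904 to 0.177). Other processing gave 0.0299 with FPKM of at least 5 in 3 libraries, 0.0462 with median-of-ratios scaling, 0.00904 under quantile normalization and 0.0398 within the groups compared alone. Of the replication-independent and linker histone genes, 6 of 10 were higher and 0 lower (camera adjusted p = 0.0207, and adjusted p = 0.177 with an estimated correlation). The linker histone genes rose, H1F0 from 39.2 ± 18.2 to 165 ± 5.46 FPKM and HIST1H1C from 2.88 ± 0.116 to 14.6 ± 2.08 FPKM. Of the immediate-early and AP-1 genes, 13 of 21 were higher and 3 lower (camera adjusted p = 0.0207, and adjusted p = 0.177 with an estimated correlation). IER3 rose from 8.12 ± 0.788 to 161 ± 14.5 FPKM, and JUN from 3.19 ± 0.151 to 15.7 ± 0.638 FPKM. This list was not called under quantile normalization (adjusted p = 0.089 with it, range 0.00457 to 0.177). Of the metallothioneins, 4 of 6 were higher and 0 lower (camera adjusted p = 0.0487, and adjusted p = 0.177 with an estimated correlation). The adjusted p of this list was 0.061 without untreated Jurkat replicate 3 and 0.054 without untreated Molt-4 replicate 2 (range 0.0111 to 0.177). The call was lost at 0.0574 with a pseudocount of 0.1, 0.0629 with no filter on low values and 0.0555 with equal totals without 7SL RNA. Among the targets of chidamide, HDAC3 rose from 50.4 ± 1.57 to 68.8 ± 1.26 FPKM (adjusted p = 1.19e-05). HDAC1 was at 303 ± 27.6 FPKM untreated and 317 ± 6.21 FPKM treated, HDAC2 at 212 ± 2.29 FPKM untreated and 226 ± 4.51 FPKM treated and HDAC10 at 49.8 ± 7.9 FPKM untreated and 45 ± 1.87 FPKM treated (adjusted p = 0.404, 0.125 and 0.373). HDAC1 and HDAC2 were called higher in Jurkat in other scalings, HDAC1 at 0.000434 under quantile normalization and 0.0294 with equal totals without 7SL RNA (range 0.000434 to 0.958) and HDAC2 at 0.0016 under quantile normalization and 0.00449 with equal totals without 7SL RNA (range 0.0016 to 0.29). Of the deacetylase genes, 9 of 18 were higher and 0 lower (camera adjusted p = 0.0862). That list reached an adjusted p of 0.0358 with FPKM of at least 5 in 3 libraries and 0.0151 under quantile normalization (range 0.0151 to 0.177). HDAC9 rose from 5.83 ± 3.16 to 24.1 ± 5.25 FPKM.

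T-cell genes moved apart in Jurkat. Of the T-cell receptor and proximal signalling genes, 12 of 29 were higher and 14 lower (camera adjusted p = 0.198). CD247 fell from 101 ± 2.12 to 39.6 ± 2.44 FPKM and CD7 from 85.3 ± 11.2 to 33.9 ± 1.48 FPKM. CD28 rose from 33.2 ± 5.93 to 68.4 ± 1.86 FPKM. CD3G fell from 87.2 ± 4.72 to 39.6 ± 4.28 FPKM (adjusted p = 5.5e-07). Of the immature thymocyte genes, 10 of 23 were higher and 11 lower (camera adjusted p = 0.309). CD1E fell from 304 ± 31.1 to 50.9 ± 0.367 FPKM, and CD1B from 32 ± 5.24 to 8.4 ± 0.795 FPKM. Of the T-ALL transcription factor genes, 13 of 19 were higher and 4 lower (camera adjusted p = 0.034, and adjusted p = 0.236 with an estimated correlation). GATA3 rose from 33.5 ± 3.91 to 148 ± 14.6 FPKM and RUNX3 from 16.7 ± 1.94 to 40.6 ± 2.52 FPKM. LMO1 fell from 6.73 ± 0.827 to 1.13 ± 0.524 FPKM. Markers of other blood lineages were measured alongside. Of the NK and cytotoxic genes, 8 of 12 were higher and 2 lower (8 and 3 adjusted over the list alone) (camera adjusted p = 0.0298, and adjusted p = 0.158 with an estimated correlation). NCAM1 rose from 0.107 ± 0.0929 to 25.3 ± 2.95 FPKM, and GZMA from 2.5 ± 1.04 to 19.8 ± 3.19 FPKM. Of the B-cell markers, 0 of 8 were higher and 4 lower (camera adjusted p = 0.064). The members that fell included IGLL1, VPREB1 and CD79A, the last from 27.4 ± 2.55 to 11.6 ± 0.431 FPKM. The B-cell list reached an adjusted p of 0.048 without untreated Jurkat replicate 2, 0.040 without treated Jurkat replicate 3, 0.0436 without treated Molt-4 replicate 1, 0.0493 without treated Molt-4 replicate 2 and 0.0474 without treated Molt-4 replicate 3 (range 0.0148 to 0.262). Other processing gave 0.0277 with FPKM of at least 5 in 3 libraries, 0.0148 under quantile normalization, 0.0468 with equal totals without 7SL RNA and 0.0292 within the groups compared alone. Of the myeloid markers, 6 of 11 were higher and 0 lower (camera adjusted p = 0.12). Of the epithelial markers, 3 of 9 were higher and 0 lower (camera adjusted p = 0.309). Their median of 0.04 turned to -0.15 under quantile normalization. Of the fibroblast and endothelial markers, 5 of 6 were higher and 1 lower (camera adjusted p = 0.0696). COL1A1 rose from 1.29 ± 0.744 to 40.8 ± 4.99 FPKM, and PECAM1 fell from 78.9 ± 4.8 to 41.5 ± 3.34 FPKM. Of the erythroid and megakaryocyte markers, 10 of 20 were higher and 0 lower (camera adjusted p = 0.04999, and adjusted p = 0.243 with an estimated correlation). The adjusted p of this list was 0.0768 without untreated Jurkat replicate 3, 0.0534 without untreated Molt-4 replicate 1, 0.0552 without untreated Molt-4 replicate 2 and 0.0505 without untreated Molt-4 replicate 3 (range 0.00519 to 0.325). The call was lost at 0.094 with no filter on low values, 0.325 under quantile normalization and 0.0747 with equal totals without 7SL RNA. The globin genes in it were uneven among the treated libraries. HBB was at 0, 18.2 and 20.2 FPKM in treated replicates 1, 2 and 3, and HBA2 at 3.51, 37.8 and 36.7 FPKM. The call of HBB was lost without treated replicate 2 or 3 (adjusted p = 0.0707 and 0.072, range 2.21e-08 to 0.072).

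In the limma fit, 4277 genes were higher and 3509 lower with chidamide in Jurkat out of 13840 tested (3589 and 4039 under quantile normalization, 3191 and 3353 with FPKM of at least 5 in 3 libraries, 4839 and 2922 with equal totals without 7SL RNA), or 1172 and 347 with a change of at least 2-fold as well. Besides CDKN1A, NCAM1 and COL1A1, the largest rises were those of the kinase gene SGK1, from 0.933 ± 0.169 to 42.2 ± 2.61 FPKM, SHISA2, from 6.33 ± 1.56 to 139 ± 3.3 FPKM, and ENC1, from 1.33 ± 0.199 to 43.1 ± 4.9 FPKM (adjusted p between 1.76e-11 and 2.37e-10). Besides IGLL1 and DNTT, the largest falls included the costimulatory receptor gene TNFRSF4, from 15.6 ± 5.48 to 0.55 ± 0.259 FPKM (adjusted p = 9.77e-08). They also included 3 short non-coding RNA genes, for which FPKM is an uncertain measure. SCARNA16 went from 84.1 ± 5.12 FPKM and SNORD17 from 11.6 ± 3.4 FPKM to being listed at 0, and SNORD3B-2 fell from 25.6 ± 9.1 to 1.52 ± 1.68 FPKM. Without untreated Jurkat replicate 3, 4501 genes were higher and 3575 lower.

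**Figure D1:**
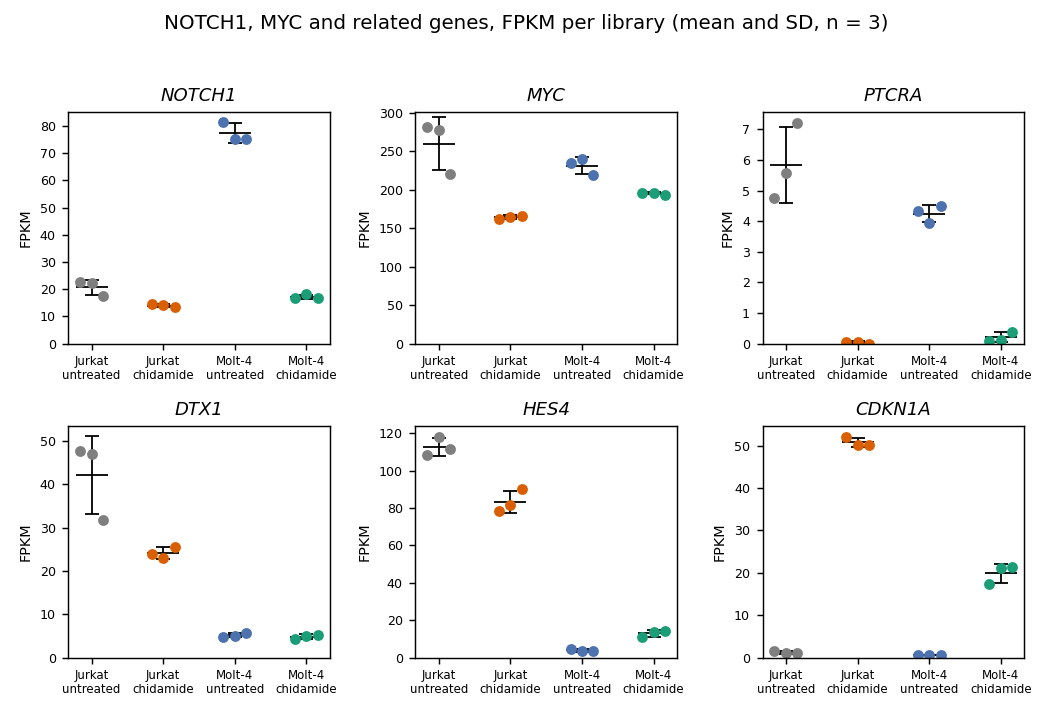
FPKM of NOTCH1, MYC, PTCRA, DTX1, HES4 and CDKN1A in each of the 12 libraries, with 1 point per library and the mean and SD of 3 libraries as black lines, on linear axes that start at 0. NOTCH1 lay at 77.3 ± 3.72 FPKM untreated and 17.2 ± 0.796 FPKM treated in Molt-4, and at 20.8 ± 2.72 FPKM untreated and 14 ± 0.595 FPKM treated in Jurkat.

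The second comparison asked the same of Molt-4. NOTCH1 fell from 77.3 ± 3.72 to 17.2 ± 0.796 FPKM (log2 change -2.11 ± 0.087, adjusted p = 1.83e-09). This fall was larger than in Jurkat. MYC fell from 231 ± 11 to 195 ± 1.33 FPKM (log2 change -0.24 ± 0.079, adjusted p = 0.0182). CDKN1A rose from 0.637 ± 0.0503 to 19.9 ± 2.2 FPKM (log2 change 3.67 ± 0.11, adjusted p = 1.56e-10), while RAG1 fell from 89.3 ± 4.05 to 1.91 ± 0.141 FPKM (log2 change -4.96 ± 0.068, adjusted p = 3.69e-13). Genes of DNA replication and DNA repair fell as groups, and neuronal, MHC class II, immediate-early, myeloid and cytotoxic genes rose.

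The call of MYC in Molt-4 depended on single libraries, with an adjusted p of 0.0517 without untreated Molt-4 replicate 1, 0.0636 without untreated Molt-4 replicate 2 and 0.0503 without treated Molt-4 replicate 3 (range 0.000167 to 0.0636). PTCRA fell from 4.25 ± 0.287 to 0.203 ± 0.163 FPKM and BCAT1 from 67.3 ± 3.04 to 34.1 ± 2.52 FPKM (adjusted p between 6.82e-08 and 4.08e-05). Other NOTCH1 targets rose. HES4 went from 3.98 ± 0.725 to 13.1 ± 1.84 FPKM, HEY1 from 0.717 ± 0.385 to 4.31 ± 0.795 FPKM and NRARP from 4.4 ± 0.87 to 11.9 ± 0.955 FPKM. NOTCH3 rose from 2.17 ± 0.543 to 5.8 ± 0.916 FPKM, IL7R from 0.163 ± 0.231 to 2.78 ± 0.842 FPKM and TRIB2 from 28.3 ± 2.78 to 101 ± 5.24 FPKM. The adjusted p of these 6 genes lay between 1.08e-08 and 1.61e-05. HES1 rose from 31.2 ± 0.47 to 42.3 ± 2.56 FPKM (adjusted p = 0.0154). That call was lost without treated Molt-4 replicate 2 (adjusted p = 0.0575, range 0.000365 to 0.089) and with a pseudocount of 0.1. DTX1 was at 5.12 ± 0.47 FPKM untreated and 4.84 ± 0.531 FPKM treated (adjusted p = 0.699), and was called lower at an adjusted p of 0.00483 under quantile normalization (range 0.00483 to 0.976). Of the NOTCH1 targets, 11 of 22 were higher and 5 lower (camera adjusted p = 0.258). Of the NOTCH pathway genes, 15 of 33 were higher and 8 lower (camera adjusted p = 0.673). The median of the pathway genes was 0.18, and -0.011 under quantile normalization. Of the MYC-activated genes, 1 of 52 were higher and 44 lower (1 and 46 adjusted over the list alone) (camera adjusted p = 1.39e-11, and adjusted p = 0.23 with an estimated correlation). Their median log2 change was -0.65. The pseudouridine synthase gene PUS7 fell from 32 ± 1.73 to 11.5 ± 0.507 FPKM, and SRM from 164 ± 2.6 to 76 ± 3.97 FPKM. CCND2 rose from 0.61 ± 0.0173 to 6.28 ± 0.344 FPKM. Of the ribosomal protein genes, 6 of 64 were higher and 29 lower (6 and 28 adjusted over the list alone) (camera adjusted p = 0.000187, and adjusted p = 0.491 with an estimated correlation). Their median was -0.12.

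Of the DNA replication genes, 2 of 39 were higher and 30 lower (camera adjusted p = 3.43e-08, and adjusted p = 0.00319 with an estimated correlation). TYMS fell from 243 ± 0.493 to 149.7 ± 0.318 FPKM. Of the repair genes, 1 of 32 were higher and 20 lower (camera adjusted p = 2.2e-05, and adjusted p = 0.0254 with an estimated correlation). NBN fell from 28.8 ± 2.51 to 15.6 ± 0.711 FPKM. Of the mitotic genes, 4 of 40 were higher and 15 lower (camera adjusted p = 0.00414, and adjusted p = 0.0305 with an estimated correlation). The cyclin gene CCNA2 fell from 94.8 ± 0.823 to 63.2 ± 1.72 FPKM. The call of the mitotic list was lost under quantile normalization (adjusted p = 0.324 with it, range 0.000362 to 0.324). Of the CDK inhibitors, 4 of 6 were higher and 1 lower (camera adjusted p = 0.149). That list reached an adjusted p of 0.036 under quantile normalization (range 0.036 to 0.278). Of the p53 target genes, 14 of 23 were higher and 3 lower (camera adjusted p = 0.0392, and adjusted p = 0.193 with an estimated correlation). This call was lost within the Molt-4 groups alone (adjusted p = 0.0519) and without untreated Jurkat replicate 3 (0.0566, range 0.0175 to 0.193). Of the pro-apoptotic genes, 10 of 23 were higher and 3 lower (camera adjusted p = 0.209). For this list the adjusted p was 0.0463 under quantile normalization (range 0.0463 to 0.256). TNFRSF10B rose from 3.68 ± 0.576 to 16 ± 1.12 FPKM and BMF from 2.12 ± 0.774 to 10.6 ± 0.787 FPKM. Of the anti-apoptotic genes, 5 of 10 were higher and 1 lower (camera adjusted p = 0.294). BCL2L1 rose from 79.4 ± 2.74 to 112 ± 3.65 FPKM (adjusted p = 7.52e-06).

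Of the neuronal genes, 28 of 35 were higher and 3 lower (camera adjusted p = 3.43e-08, and adjusted p = 0.00319 with an estimated correlation). The synaptophysin gene SYP rose from 3.01 ± 0.315 to 38.1 ± 1.75 FPKM. Of the MHC class II genes, 7 of 10 were higher and 0 lower (camera adjusted p = 0.00293, and adjusted p = 0.0456 with an estimated correlation). Of the MHC class I genes, 8 of 15 were higher and 6 lower (camera adjusted p = 0.435). HLA-B rose from 3.9 ± 2.86 to 192 ± 23.1 FPKM. Of the immediate-early genes, 17 of 21 were higher and 2 lower (camera adjusted p = 3.58e-05, and adjusted p = 0.0254 with an estimated correlation). JUN rose from 2.94 ± 0.335 to 30.5 ± 1.16 FPKM. Of the metallothioneins, 6 of 6 were higher and 0 lower (camera adjusted p = 0.00293, and adjusted p = 0.0391 with an estimated correlation). MT1X rose from 33.5 ± 3.74 to 55.6 ± 7.05 FPKM. Of the histone acetyltransferase and reader genes, 1 of 13 were higher and 6 lower (camera adjusted p = 0.0266, and adjusted p = 0.111 with an estimated correlation). KAT2A fell from 61.1 ± 3.07 to 34.9 ± 2.39 FPKM. The call of this list was lost under quantile normalization (adjusted p = 0.155) and with FPKM of at least 5 in 3 libraries (0.0676, range 0.0106 to 0.155). Of the cholesterol biosynthesis genes, 3 of 24 were higher and 14 lower (camera adjusted p = 0.00202, and adjusted p = 0.431 with an estimated correlation). ACAT2 fell from 85.9 ± 4.17 to 35.1 ± 2.5 FPKM. This call was lost under quantile normalization (adjusted p = 0.067 with it, range 0.00024 to 0.431). HDAC1 rose from 235 ± 15 to 266 ± 6.1 FPKM (adjusted p = 0.0332), and HDAC3 from 77.6 ± 3.76 to 87.3 ± 2.38 FPKM (adjusted p = 0.012). HDAC10 fell from 34.4 ± 4.26 to 26.4 ± 2.87 FPKM (adjusted p = 0.018). These 3 calls were lost without a single library, and those of HDAC1 and HDAC3 also with median-of-ratios scaling (adjusted p = 0.124 and 0.0862). HDAC1 had an adjusted p of 0.115 without untreated Molt-4 replicate 1, 0.0967 without untreated Molt-4 replicate 2, 0.0808 without treated Molt-4 replicate 1 and 0.094 without treated Molt-4 replicate 3 (range 0.000115 to 0.124). HDAC3 had an adjusted p of 0.0541 without treated Molt-4 replicate 3 (range 0.0013 to 0.0862). HDAC10 had an adjusted p of 0.0614 without untreated Molt-4 replicate 1, 0.0718 without untreated Molt-4 replicate 3 and 0.0803 without treated Molt-4 replicate 1 (range 0.00576 to 0.0803). HDAC2 was at 173 ± 10.4 FPKM untreated and 161 ± 5.13 FPKM treated (adjusted p = 0.104), and had an adjusted p of 0.0293 without untreated Molt-4 replicate 1 (range 0.0171 to 0.451), and of 0.0171 with median-of-ratios scaling. Of the deacetylase genes, 11 of 18 were higher and 3 lower (camera adjusted p = 0.296). HDAC5 rose from 9.13 ± 0.625 to 39.1 ± 0.653 FPKM.

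The Molt-4 libraries carried erythroid transcripts before treatment. Whether a changed mix of cells moved the other lineage genes below was not tested. The fetal globin gene HBG2 was at 6000.1 ± 289.8 FPKM, and the embryonic globin genes HBZ and HBE1 at 677 ± 16.8 and 381 ± 15.2 FPKM. Of the erythroid and megakaryocyte markers, 14 of 20 were higher after chidamide and 2 lower (camera adjusted p = 0.00135, and adjusted p = 0.0953 with an estimated correlation). HBG2 rose to 14075 ± 221 FPKM, HBE1 rose to 4446 ± 73.8 FPKM and HBZ fell to 555 ± 9.86 FPKM (adjusted p = 4.54e-09, 5.75e-11 and 0.000441). The haem synthesis gene ALAS2 rose from 13.3 ± 2.72 to 118 ± 6.3 FPKM. Reads of HBA1 and HBA2, and of HBG1 and HBG2, can be shared between near-identical copies, so the level of each is uncertain. Of the myeloid markers, 11 of 11 were higher and 0 lower (camera adjusted p = 0.000262, and adjusted p = 0.0254 with an estimated correlation). The lysozyme gene LYZ rose from 0.677 ± 0.251 to 62.9 ± 0.906 FPKM, and CD68 from 5.58 ± 0.33 to 27.5 ± 2.32 FPKM. Of the NK and cytotoxic markers, 10 of 12 were higher and 0 lower (camera adjusted p = 0.000367, and adjusted p = 0.0254 with an estimated correlation). Of the epithelial markers, 8 of 9 were higher and 0 lower (camera adjusted p = 0.00093, and adjusted p = 0.0423 with an estimated correlation). The E-cadherin gene CDH1 rose from 1.43 ± 0.839 to 22.3 ± 0.486 FPKM, and KRT8 from 28.1 ± 3.32 to 105 ± 1.05 FPKM. Of the fibroblast and endothelial markers, 5 of 6 were higher and 0 lower (6 and 0 adjusted over the list alone) (camera adjusted p = 0.00232, and adjusted p = 0.0381 with an estimated correlation). THY1 rose from 0.030 ± 0.010 to 28.7 ± 4.61 FPKM. Of the B-cell markers, 5 of 8 were higher and 2 lower (camera adjusted p = 0.349). VPREB1 fell from 28.1 ± 1.61 to 1.71 ± 0.0569 FPKM, and CD79A rose from 2.85 ± 0.406 to 13.3 ± 1.31 FPKM. Of the T-cell receptor genes, 16 of 29 were higher and 9 lower (17 and 9 adjusted over the list alone) (camera adjusted p = 0.392). CD28 rose from 0.667 ± 0.18 to 14.9 ± 1.77 FPKM. CD3G fell from 47.7 ± 3.38 to 26.3 ± 2.26 FPKM. Of the immature thymocyte genes, 12 of 23 were higher and 11 lower (camera adjusted p = 0.264), with a median of 0.35 and a mean of -0.56. DNTT fell from 75.4 ± 1.8 to 1.8 ± 0.324 FPKM, and CD1B from 87.5 ± 3.15 to 7.25 ± 1.53 FPKM. Of the T-ALL transcription factor genes, 12 of 19 were higher and 3 lower (camera adjusted p = 0.0124, and adjusted p = 0.193 with an estimated correlation). RUNX3 rose from 0.853 ± 0.261 to 17.1 ± 0.81 FPKM, and GATA3 from 23.6 ± 4.55 to 169 ± 16.8 FPKM.

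**Figure D2:**
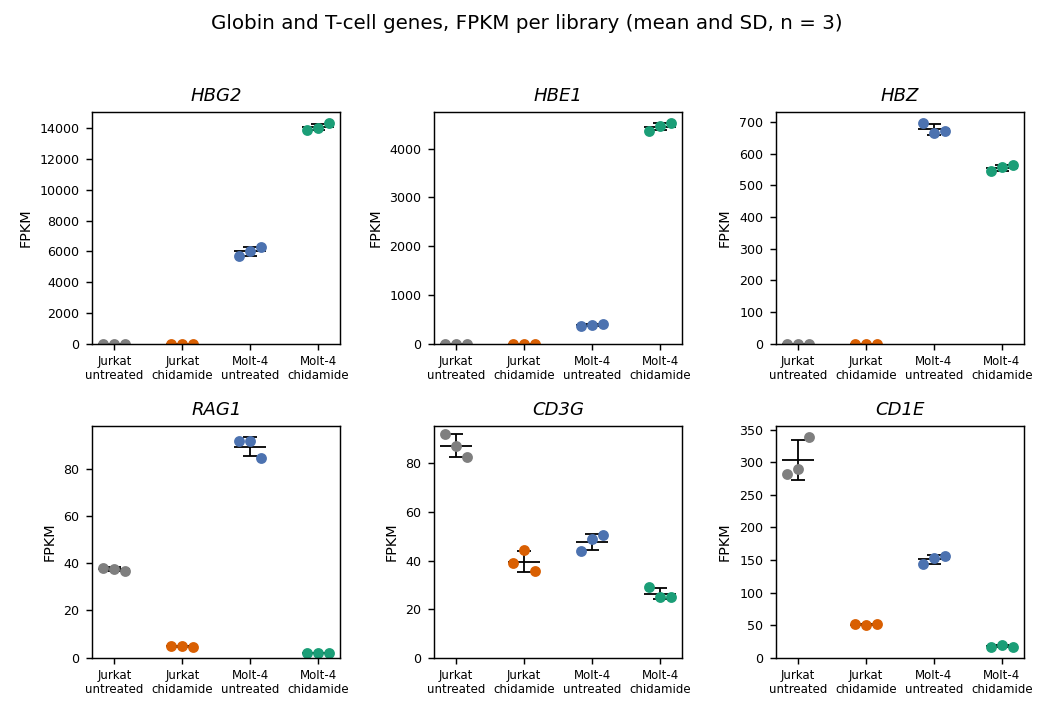
FPKM of the globin genes HBG2, HBE1 and HBZ and of the T-cell and thymocyte genes RAG1, CD3G and CD1E in each of the 12 libraries, with 1 point per library and the mean and SD of 3 libraries as black lines, on linear axes that start at 0. The globin genes were high in both Molt-4 groups, which also expressed CD3G at 47.7 ± 3.38 FPKM untreated and 26.3 ± 2.26 FPKM treated.

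In Molt-4, 4903 genes were higher and 3401 lower with chidamide, or 1713 and 185 with a change of at least 2-fold. The largest rise was that of PRG2, the eosinophil major basic protein gene, from 9.77 ± 0.583 to 1518 ± 35.8 FPKM (adjusted p = 3.69e-13). Next came the microRNA gene MIR6843, from 2.86 ± 0.923 to 343 ± 18.4 FPKM, uncertain for so short a gene. CPXM1 followed, from 0.50 ± 0.131 to 79.8 ± 2.5 FPKM. The trypsinogen gene PRSS2, whose paralogs can share reads, rose from 0.593 ± 0.326 to 76.7 ± 3.71 FPKM. HLA-B and LYZ completed the first 6. Besides RAG1, DNTT, CD1B and VPREB1, the largest falls were those of IGLL1, from 79.9 ± 1.81 to 2.65 ± 0.341 FPKM, and SH3TC1, from 33.2 ± 2.28 to 2.18 ± 0.32 FPKM (adjusted p between 4.96e-11 and 1.46e-09). Of the called genes 59.0% were higher, and 41.3% (3540 higher, 5039 lower) after quantile normalization, which shifted the median change of all genes by -0.17. Smaller log2 changes depend on the scaling.

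The responses of the lines overlapped. The rises common to both, ranked by the smaller change, were led by COL1A1, NRGN, TMEM59L, CDKN1A and L1CAM. NRGN rose from 6.74 ± 0.56 to 127 ± 4.64 FPKM in Jurkat and from 1.34 ± 0.412 to 53 ± 3.25 FPKM in Molt-4. TMEM59L rose from 0.487 ± 0.161 to 24.2 ± 1.84 FPKM in Jurkat and from 0.090 ± 0.0361 to 15.7 ± 0.714 FPKM in Molt-4. The common falls were led by DNTT, IGLL1, SH3TC1, CXorf49 and RAG1. SH3TC1 fell from 50.1 ± 8.85 to 5.07 ± 0.867 FPKM in Jurkat. CXorf49 fell from 24.4 ± 8.43 to 1.93 ± 0.38 FPKM in Jurkat and from 67.7 ± 8.83 to 6.21 ± 1.37 FPKM in Molt-4. Its near-identical copy CXorf49B had the same values in the Jurkat and the treated Molt-4 libraries and was listed at 0 in untreated Molt-4, so both are uncertain. In all, 3007 genes were called higher in both lines, against 1515 for independent lists, and 2249 lower in both, against 862. Under quantile normalization these were 2090 and 2787. Opposite directions were called for 133 and 261 genes, against 1051 and 1243. With at least 2-fold changes, 662 were higher and 87 lower. Across the 13840 genes, which are not independent, the log2 changes of the lines correlated (Pearson r 0.638, Spearman rho 0.666). These comparisons share no library, but a shared fit set their spread, so independent lists are no exact baseline.

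**Figure D3:**
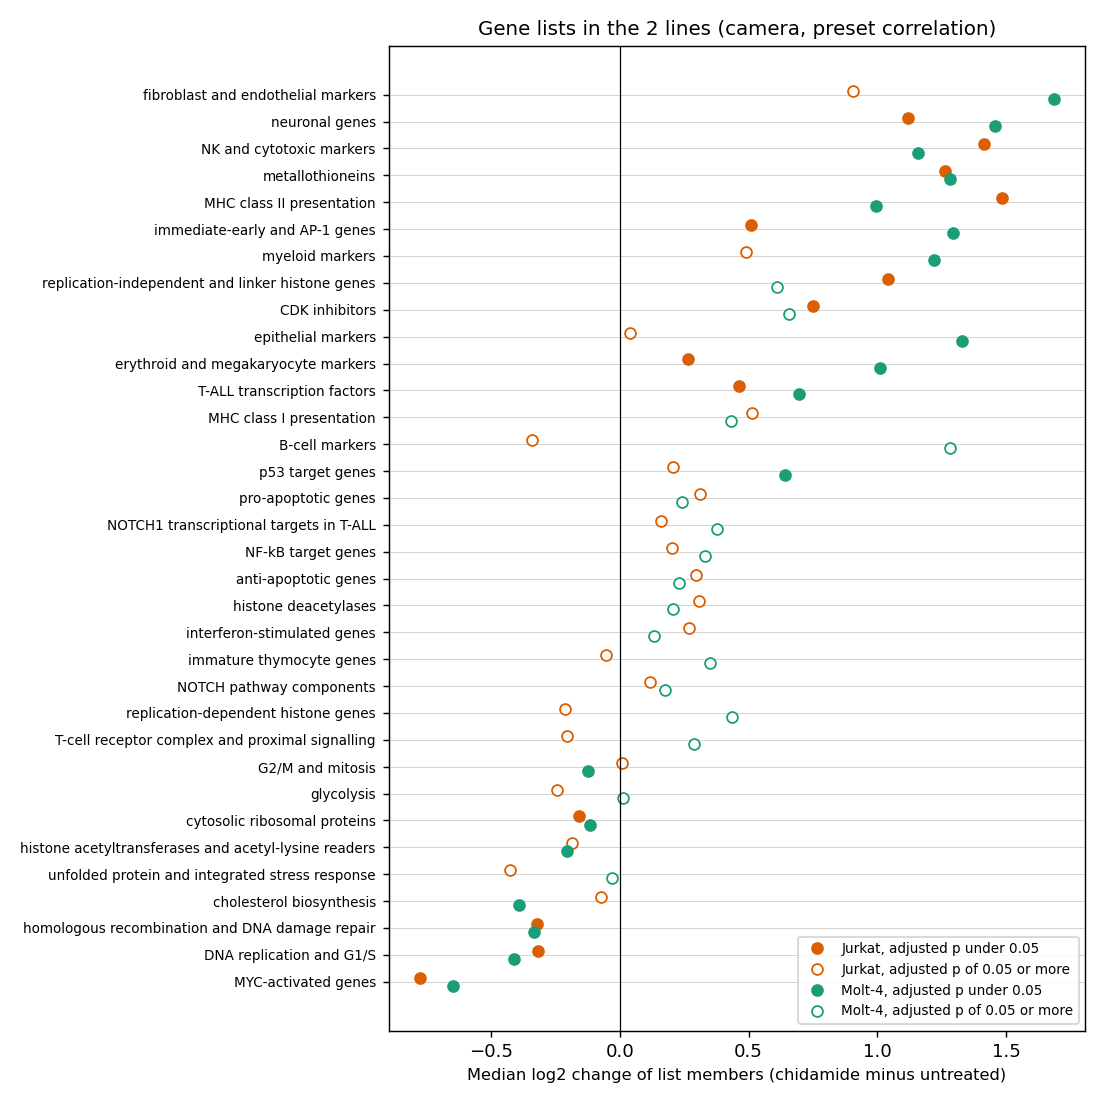
Median log2 change of the tested members of each of the 34 gene lists with chidamide, in log2(FPKM + 1) units, for Jurkat (orange) and Molt-4 (green), with filled circles for lists called by camera with the preset correlation and open circles for the others. The MYC-activated genes had the lowest medians in both lines, at -0.77 in Jurkat and -0.65 in Molt-4.

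The next test was whether responses differed between the lines. The fall of NOTCH1 was larger in Molt-4, by a log2 difference of -1.58 ± 0.12 (adjusted p = 2.12e-06). That of MYC was smaller, by 0.41 ± 0.11 (adjusted p = 0.0148). HES4, NOTCH3 and IL7R moved up in Molt-4 relative to Jurkat, by 1.93 ± 0.16, 1.11 ± 0.19 and 1.55 ± 0.24 (adjusted p between 3.48e-06 and 0.000777). CD247, CD7 and BCL2L1 fell in Jurkat and rose in Molt-4, with differences of 1.63 ± 0.079, 2.02 ± 0.12 and 1.06 ± 0.075 (adjusted p between 5.66e-08 and 1.0e-06). A changed mix of Molt-4 cells as a cause was not tested.

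PRG2 and CPXM1 rose in Molt-4 by 7.14 and 5.75 on the log2 scale, and the differences from Jurkat were 7.21 ± 0.14 and 5.85 ± 0.12 (adjusted p between 1.8e-11 and 3.16e-11). In the opposite direction, the actin-bundling protein gene FSCN1 rose in Jurkat from 1.52 ± 0.262 to 26.6 ± 0.793 FPKM, and in Molt-4 it was at 68.3 ± 2.35 FPKM untreated and 64.3 ± 1.35 FPKM treated (adjusted p = 1.52e-09 for the difference). FRG2B rose from 0.090 ± 0.0819 to 14 ± 1.6 FPKM in Jurkat and was at 0.0367 ± 0.0635 FPKM untreated and 0.227 ± 0.114 FPKM treated in Molt-4 (adjusted p = 3.03e-08 for the difference). Its Molt-4 adjusted p was 0.048 without treated Molt-4 replicate 2 (range 0.0191 to 0.674). TMEM158 was listed at 0 in untreated Jurkat and at 4.66 ± 0.733 FPKM after treatment, and fell from 15.1 ± 1.92 to 7.85 ± 0.514 FPKM in Molt-4 (adjusted p = 5.66e-08 for the difference). SCARNA16 was listed at 0 outside untreated Jurkat. Of the NOTCH1 targets, 13 of 22 were higher in Molt-4 than in Jurkat in their response and 3 lower (camera adjusted p = 0.0234, and adjusted p = 0.114 with an estimated correlation). This call was lost with a pseudocount of 0.1 (adjusted p = 0.0655) and with FPKM of at least 5 in 3 libraries (0.0524, range 0.00707 to 0.114). Of the T-cell receptor genes, 13 of 29 were higher and 3 lower (15 and 3 adjusted over the list alone) (camera adjusted p = 0.00411, and adjusted p = 0.173 with an estimated correlation). The list of MYC-activated genes was not called (camera adjusted p = 0.0952), but it was without untreated Jurkat replicate 3 (adjusted p = 2.01e-06) and under quantile normalization (0.00846, range 2.01e-06 to 0.832).

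In limma's test of the difference, 4416 genes were called, 2745 higher and 1671 lower in Molt-4, or 1202 with a difference of at least 2-fold. Of these 4416 genes, 394 had opposite calls in the lines. The share of higher calls was 62.2%. It was 45.9% after quantile normalization (2271 higher, 2678 lower), which shifted the median by -0.10, and 50.9% with equal totals without 7SL RNA (2255 and 2178). Without untreated Jurkat replicate 3, 4926 genes differed.

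Before treatment the genes furthest higher in Molt-4 than in Jurkat were globin genes. HBG2, HBG1 and HBZ were at 6000.1 ± 289.8, 1675 ± 39.5 and 677 ± 16.8 FPKM in Molt-4 and listed at 0 in Jurkat. HBA1 and HBA2 were at 1472 ± 54.5 and 515 ± 13.5 FPKM in Molt-4, against 0.63 ± 0.341 and 0.353 ± 0.325 FPKM in Jurkat. Higher in Jurkat were the myosin gene MYO7B (511 ± 46.2 FPKM in Jurkat and 3.7 ± 0.618 FPKM in Molt-4), the extracellular matrix gene FBLN2 (53.7 ± 6.32 FPKM in Jurkat and 0.14 ± 0.199 FPKM in Molt-4) and THY1 (43.9 ± 2.22 FPKM in Jurkat and 0.030 ± 0.010 FPKM in Molt-4). RNF212 and SCARNA16 were at 30.5 ± 2.2 and 84.1 ± 5.12 FPKM in Jurkat and listed at 0 in Molt-4. These 10 genes had an adjusted p between 4.46e-19 and 1.08e-07. NOTCH1 was higher in Molt-4, at 77.3 ± 3.72 against 20.8 ± 2.72 FPKM (adjusted p = 2.15e-09). MYC was at 231 ± 11 FPKM in Molt-4 and 259.7 ± 34.2 FPKM in Jurkat (adjusted p = 0.0939), and had an adjusted p of 0.000152 without untreated Jurkat replicate 3 (range 0.000152 to 0.667), and of 0.0319 under quantile normalization and 0.0276 with equal totals without 7SL RNA.

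Of the erythroid and megakaryocyte markers, 16 of 20 were higher in untreated Molt-4 and 1 lower (camera adjusted p = 3.62e-10, and adjusted p = 0.0397 with an estimated correlation). Their median log2 difference was 4.72. Of the T-cell receptor genes, 7 of 29 were higher in untreated Molt-4 and 20 lower (camera adjusted p = 0.00863, and adjusted p = 0.317 with an estimated correlation). Of the replication-independent and linker histone genes, 7 of 10 were higher in untreated Molt-4 and 2 lower (camera adjusted p = 0.0074, and adjusted p = 0.206 with an estimated correlation). Of the replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail, 11 of 17 were higher in untreated Molt-4 and 1 lower (camera adjusted p = 0.0074, and adjusted p = 0.125 with an estimated correlation). Of the DNA replication genes, 19 of 39 were higher in untreated Molt-4 and 6 lower (camera adjusted p = 0.0419, and adjusted p = 0.206 with an estimated correlation). This call was lost with equal totals without 7SL RNA (adjusted p = 0.0869 with them, range 0.0168 to 0.206). Of the ribosomal protein genes, 34 of 64 were higher in untreated Molt-4 and 10 lower (camera adjusted p = 0.0074, and adjusted p = 0.742 with an estimated correlation). The direction turned under quantile normalization (adjusted p = 0.972 with it, range 3.48e-05 to 0.972). Of the epithelial markers, 6 of 9 were higher in untreated Molt-4 and 2 lower (camera adjusted p = 0.0419, and adjusted p = 0.287 with an estimated correlation). KRT8 was at 28.1 ± 3.32 FPKM in Molt-4 and 0.0733 ± 0.127 FPKM in Jurkat. The epithelial list had an adjusted p of 0.0606 without untreated Jurkat replicate 2 and 0.0505 without untreated Jurkat replicate 3 (range 0.0048 to 0.296), and 0.0673 with a pseudocount of 0.1, 0.296 with no filter on low values, 0.0951 with median-of-ratios scaling, 0.113 under quantile normalization and 0.056 within the groups compared alone. In limma's test 9044 genes differed between the untreated lines, 3857 higher and 5187 lower in Molt-4 (4646 and 4344 with median-of-ratios scaling), or 2707 with a difference of at least 2-fold.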

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

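Most of the tests weighed here were chosen only after the result was seen: those of an erythroid line, of a mix of cells, of the share of erythroid cells, of treated RNA, of the depth of a library, of scaling and of deeper sequencing. Those of Molt-4 RNA and of genomic DNA were written before. The named genes below had a response to chidamide that differed between the lines in limma's test of the difference. The number after each gene is the log2 change in Molt-4 minus that in Jurkat, with an SE between 0.062 and 1.11. Ranges of adjusted p are over all alternatives. Genes that fell in Jurkat and rose in Molt-4 were CXorf49B (5.89), CD79A (3.07), CD7 (2.02), HES4 (1.93), CD247 (1.63), PECAM1 (1.55) and BCL2L1 (1.06), with an adjusted p between 4.68e-08 and 6.92e-06. A gene that rose in Jurkat and fell in Molt-4 was TMEM158 (-3.35), with an adjusted p of 5.66e-08. The value of CXorf49B is uncertain, since CXorf49 is a near-identical copy.

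Genes that rose in both lines, and more in Molt-4, were THY1 (3.65), MIR6843 (3.09, uncertain), HLA-B (2.94), CD28 (2.23), RUNX3 (2.06), SYP (1.83) and CCND2 (1.51). Further such genes were BIRC3 (1.23), HLA-DPB1 (1.17), HDAC5 (1.15), CD68 (1.13), IFI6 (1.1), HBG2 (1.07) and KRT8 (1.01). Others were JUN (1.01), TRIB2 (0.78), TNFRSF10B (0.73), GATA3 (0.69), MAML3 (0.51) and NRGN (0.50), with an adjusted p between 7.87e-09 and 0.029. For the difference of NRGN the adjusted p was between 0.0512 and 0.0699 without any 1 of 7 of the 12 libraries (range 0.00194 to 0.0961). Genes that rose in both lines and rose less in Molt-4 were SGK1 (-2.34), NCAM1 (-2.01), SCG2 (-1.70), HLA-DRA (-1.31), ADAM10 (-1.26), CD83 (-1.19), ENC1 (-0.99) and SLC2A3 (-0.85). The others were SHISA2 (-0.85), CDKN1A (-0.84), CDKN2D (-0.72), HIST1H1C (-0.65), IER3 (-0.61), GADD45A (-0.43), TOP2A (-0.35) and HDAC3 (-0.28), with an adjusted p between 2.26e-07 and 0.0109. Genes that fell in both lines and fell less in Molt-4 were TNFRSF4 (2.44), TERT (2.19), MYO7B (1.52), IGLL1 (1.16), BCAT1 (0.86) and USP18 (0.60). Smaller differences were those of PTCRA (0.56), LYAR (0.53), RPS23 (0.49), SKP2 (0.47) and MYC (0.41), with an adjusted p between 8.4e-06 and 0.0418. PTCRA had an adjusted p between 0.0538 and 0.104 without any 1 of 10 of the 12 libraries (range 0.0176 to 0.484). Genes that fell in both lines and fell more in Molt-4 were VPREB1 (-2.72), RAG1 (-2.23), CD1B (-1.64), NOTCH1 (-1.58) and CD1E (-0.50), with an adjusted p between 2.15e-08 and 0.00469.

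Genes called higher in Molt-4 and not called in Jurkat were PRG2 (7.21), CPXM1 (5.85), PRSS2 (5.78), LYZ (5.31), CDH1 (3.33) and HBE1 (3.32). Further such genes were ALAS2 (3.01), HIST1H2AI (2.85), IL7R (1.55), FBLN2 (1.21), HBG1 (1.17) and NOTCH3 (1.11), with an adjusted p between 1.8e-11 and 0.000777. Genes called higher in Jurkat and not called in Molt-4 were FRG2B (-3.54), FSCN1 (-3.54), HBA2 (-3.40) and HBA1 (-2.46), with an adjusted p between 1.52e-09 and 0.0121. Genes called lower in Jurkat and not called in Molt-4 were SCARNA16 (6.41), SNORD3B-2 (3.59), LMO1 (1.88) and DTX1 (0.69), with an adjusted p between 1.33e-11 and 0.0277. For the difference of SNORD3B-2 the adjusted p was between 0.0519 and 0.0686 without any 1 of 6 of the 12 libraries (range 0.0154 to 0.081). A gene called lower in Molt-4 and not called in Jurkat was HBZ (-0.29), with an adjusted p of 0.0102.

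Some of these calls changed with the processing. Brackets hold the adjusted p that crossed the threshold. Differences no longer called were those of CDKN1A (0.144 with a pseudocount of 0.1, range 0.000388 to 0.144), HBG2 (0.747 with a pseudocount of 0.1, range 1.32e-06 to 0.747), HBZ (0.0721 with a pseudocount of 0.1 and 0.157 under quantile normalization, range 0.00319 to 0.157) and MAML3 (0.611 with a pseudocount of 0.1 and 0.0842 with equal totals without 7SL RNA, range 0.00102 to 0.611). The same was found for DTX1 (0.565 under quantile normalization, range 0.000404 to 0.565) and FBLN2 (0.0706 under quantile normalization, range 6.04e-05 to 0.0706). Calls were also lost at 0.0961 under quantile normalization for NRGN, 0.0569 with no filter on low values, 0.0694 with median-of-ratios scaling and 0.484 under quantile normalization for PTCRA and 0.081 with a pseudocount of 0.1 and 0.0512 with no filter on low values for SNORD3B-2. The differences of SHISA2 and KRT8 lost their calls and turned to 0.94 and -0.88 with a pseudocount of 0.1 (adjusted p = 0.0689 and 0.285, ranges 0.000108 to 0.0689 and 0.000697 to 0.285). The rise of HBG2 in Jurkat, of 0.17 ± 0.057, had an adjusted p of 0.0547 without untreated Jurkat replicate 1, 0.0513 without untreated Jurkat replicate 2, 0.107 without treated Jurkat replicate 2 and 0.090 without treated Jurkat replicate 3 (range 0.00105 to 0.699), and of 0.699 under quantile normalization. HBA2 and HBA1, not called in Molt-4, had an adjusted p there of 0.0193 and 0.00626 without treated Jurkat replicate 1, and of 1.99e-05 and 1.62e-05 within the Molt-4 groups alone (ranges 1.99e-05 to 0.689 and 1.62e-05 to 0.487). HIST1H2AI was called lower in Jurkat at 0.00010 under quantile normalization, and 0.0245 without untreated Jurkat replicate 2 and 0.0415 without treated Jurkat replicate 1 (range 0.00010 to 0.35). HBE1 was called higher in Jurkat at 0.0213 with a pseudocount of 0.1 and 0.040 with equal totals without 7SL RNA, and 0.00348 without treated Jurkat replicate 3 (range 0.00348 to 0.246). FRG2B was called higher in Molt-4 at 0.0191 with a pseudocount of 0.1 (range 0.0191 to 0.674).

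In camera's test of the difference with the preset correlation, 11 lists were called. Those further up in Molt-4 included the NOTCH1 targets (13 of 22 higher, 3 lower, adjusted p = 0.0234), T-cell receptor genes (13 of 29 higher, 3 lower, 15 and 3 adjusted over the list alone, adjusted p = 0.00411) and immediate-early genes (11 of 21 higher, 1 lower, 11 and 3 adjusted over the list alone, adjusted p = 0.020). Also further up were replication-dependent histone genes (8 of 17 higher, 0 lower, adjusted p = 0.0112), B-cell markers (7 of 8 higher, 1 lower, adjusted p = 0.00359) and myeloid markers (5 of 11 higher, 0 lower, 6 and 0 adjusted over the list alone, adjusted p = 0.00538). Also further up were erythroid and megakaryocyte markers (11 of 20 higher, 5 lower, adjusted p = 0.0334), epithelial markers (7 of 9 higher, 0 lower, 8 and 0 adjusted over the list alone, adjusted p = 0.00359) and fibroblast and endothelial markers (4 of 6 higher, 0 lower, 4 and 1 adjusted over the list alone, adjusted p = 0.0334). Those further down in Molt-4 were mitotic genes (0 of 40 higher, 10 lower, adjusted p = 0.00538) and cholesterol biosynthesis (2 of 24 higher, 7 lower, 3 and 7 adjusted over the list alone, adjusted p = 0.0222). With an estimated correlation none of the 11 lists was called by camera (adjusted p between 0.0962 and 0.797), and 0 lists were called in this comparison. The list of cholesterol biosynthesis had an adjusted p of 0.206 without untreated Jurkat replicate 3 (range 0.00479 to 0.797). The list of myeloid markers had an adjusted p of 0.0578 without treated Molt-4 replicate 1 and 0.073 without treated Molt-4 replicate 3 (range 0.00114 to 0.0962). The list of erythroid and megakaryocyte markers had an adjusted p of 0.0578 without untreated Jurkat replicate 1 and 0.262 without treated Jurkat replicate 1 (range 0.00103 to 0.59). The list of fibroblast and endothelial markers had an adjusted p of 0.0505 without untreated Jurkat replicate 1 and 0.0535 without untreated Jurkat replicate 3 (range 0.0201 to 0.151). With other processing these lists were not called: NOTCH1 targets (0.0655 with a pseudocount of 0.1 and 0.0524 with FPKM of at least 5 in 3 libraries, range 0.00707 to 0.114), replication-dependent histone genes (0.0708 with a pseudocount of 0.1, range 0.00103 to 0.0962), erythroid and megakaryocyte markers (0.59 with a pseudocount of 0.1), epithelial markers (0.107 with a pseudocount of 0.1, range 0.000282 to 0.107) and fibroblast and endothelial markers (0.107 with a pseudocount of 0.1, 0.129 with no filter on low values and 0.112 with FPKM of at least 5 in 3 libraries).

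Erythroid transcripts were abundant in every Molt-4 library, with HBG2 at 6000.1 ± 289.8 FPKM untreated. An erythroid line in place of Molt-4 is excluded, because 25 of 29 T-cell receptor and signalling genes reached a mean of 5 FPKM in untreated Molt-4, against 26 in untreated Jurkat. A larger share of erythroid cells after chidamide is excluded as the whole cause of the rise, since the log2 changes of the 10 abundant erythroid genes spanned 3.83, from -0.29 to 3.54, and HBZ fell. A line that expresses both programmes and a mix of T-cell and erythroid cells cannot be told apart, because the 16 of 20 erythroid genes at 5 FPKM or more (1 in Jurkat) would appear in both and the libraries are of whole cultures, whose identity is unverified. A change in the expression of erythroid genes with chidamide may explain the rise, as a hypothesis found in the same data.

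Untreated Jurkat replicate 3 stood apart from replicates 1 and 2. Of the stress response genes, CHAC1 was at 44.8 FPKM against 3.36 and 3.68 and EDEM1 at 239 against 97.6 and 115, while H1F0 was at 60.1 against 27.5 and 29.9, and MYC at 220.3 against 281 and 278 FPKM. RNA of treated Jurkat cells is excluded as the whole cause, because genes needed unlike shares of it. The 136 strongly induced genes needed a median of 2.56% (quartiles -0.25% and 9.0%), while H1F0 needed 23.0% and MYC 51.2%. H1F0 was picked after its value was seen, and a smaller share of treated RNA is not excluded. RNA of Molt-4 cells is excluded (highest share 0% over 5 genes). So is a lower depth as the whole cause, since counting noise falls with the level. The excess variance of log2 ratios at 100 FPKM or more was at least 0.593 times that at 1 to 10 FPKM. A difference in the culture, which no label records, stays open, and no biological explanation was tested.

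More genes went from below 0.1 FPKM in all 3 untreated libraries to at least 1 FPKM in all 3 treated ones (88 in Jurkat and 136 in Molt-4) than the other way (3 and 0). Scaling is excluded, since the factors of 2 libraries of a line differed by at most 1.05. Genomic DNA is excluded, since the median of 389 olfactory receptor genes was 0 FPKM in every treated library, with at most 2.83% of them at 1 FPKM or more, against 1.8% in untreated libraries. Deeper sequencing of the treated libraries is excluded as the whole cause: it does not alter the expected FPKM, yet for genes chosen without 1 library of each group the summed FPKM of the untreated library left out was at most 0.170 times that of the treated one (0.0552 for genes below 5 FPKM). Activation of silent genes by the inhibition of histone deacetylases stays open, untested.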

How the results depend on the processing

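Equal totals without 7SL RNA were chosen after seeing the data, and the other alternatives before. The falls of NOTCH1 in both lines and of MYC in Jurkat, and the rise of CDKN1A in both, kept their direction and call under every alternative run on single genes. The 2-fold requirement was applied to counts alone. The numbers of called genes stayed within 1.5 times their value under every alternative that kept the threshold, except genes lower in the difference, 1671 and 2678 under quantile normalization. The balance of directions depended on the processing: quantile normalization gave more falls than rises in each line, in both and for the difference, a filter of FPKM of at least 5 in 3 libraries did so in Jurkat, and median-of-ratios scaling gave more genes higher than lower in untreated Molt-4. With any 1 library left out the counts were 3735 to 4501 higher and 3175 to 3575 lower in Jurkat, 4203 to 5140 and 3018 to 3660 in Molt-4, 2680 to 3195 and 2066 to 2449 in both, 3540 to 4926 for the difference and 8446 to 8947 between the untreated lines. With a change of at least 2-fold as well, fewer genes passed by construction: 1172 and 347 in Jurkat, 1713 and 185 in Molt-4, 662 and 87 in both, 1202 for the difference and 2707 between the untreated lines.

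The fall of the MYC-activated genes was called by camera in both lines with the preset correlation and not with an estimated one (adjusted p = 0.202 in Jurkat and 0.23 in Molt-4, ranges over all alternatives 3.1e-22 to 0.202 and 4.38e-16 to 0.23). The estimated correlation of the list allows for genes that vary together, but the cause was not tested. With it 4 lists were called in Jurkat (against 13), 11 in Molt-4 (against 18), 0 for the difference (against 11) and 1 between the untreated lines (against 7). With a pseudocount of 0.1 6 lists were called for the difference. Outside the fits with 1 library left out, 1230 list tests kept their side of the threshold, 65 lost and 30 gained a call, and the ribosomal protein genes of the untreated lines reversed under quantile normalization (adjusted p = 0.972, range over all alternatives 3.48e-05 to 0.972). With 1 library left out 1595 kept it, 17 lost and 20 gained it.

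For named genes 3166 tests kept their side, 27 lost and 25 gained a call, or 4395, 45 and 16 with 1 library left out. All alternatives gave the same call for 111 of the named genes in Jurkat, 107 in Molt-4 and 97 for the difference, and at least 1 changed it for 9, 13 and 23. Signs turned in these cases. HES1 in Jurkat changed by -0.17 under quantile normalization. With a pseudocount of 0.1 the differences of SHISA2, TMEM59L and KRT8 were 0.94, 0.99 and -0.88. With 1 library left out the difference of HBB ran from -1.34 (without treated Jurkat replicate 1) to 0.87, and that of LDHA from -0.14 to 0.16 (the highest without untreated Jurkat replicate 3). For these reversals the cause was not tested. Depth is unknown, so the limit it sets on genes with low values cannot be given.

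With the replicate block 4112 genes were higher and 3389 lower in Jurkat, 4755 and 3250 in Molt-4, 2849 and 2140 in both, 3917 for the difference and 8802 between the untreated lines. Same-numbered libraries did not deviate together (r across genes -0.011, -0.0096 and -0.038 in Jurkat and -0.013, -0.0099 and 0.041 in Molt-4). Only the libraries of Molt-4 replicate 3 correlated best with their own number. The labelled time runs with that number. Calls not made with the block were those of the p53 targets in Molt-4 (adjusted p = 0.0614, range 0.0175 to 0.193), the erythroid list for the difference (adjusted p = 0.0594, range 0.00103 to 0.59) and the epithelial list of the untreated lines (adjusted p = 0.0557, range 0.0048 to 0.296), HES1 in Jurkat (adjusted p = 0.0904, range 0.0025 to 0.338) and Molt-4 (adjusted p = 0.0511, range 0.000365 to 0.089), and the differences of PTCRA (adjusted p = 0.0656, range 0.0176 to 0.484) and SNORD3B-2 (adjusted p = 0.0593, range 0.0154 to 0.081). Calls gained were those of the linker histone list in Molt-4 (adjusted p = 0.0301, range 0.00264 to 0.23) and the stress response list in Jurkat (adjusted p = 0.0497, range 0.022 to 0.267). Other calls of lists and named genes did not change with it.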

Other observations

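The test of the distance between the lines was planned before its result was seen, and the counts of splits of the libraries were chosen after it. Ranges of adjusted p are over all alternatives. Lists that were not called in a line, and are not described with the comparisons above, gave the following values. Of the interferon-stimulated genes, 16 of 39 were higher and 6 lower (camera adjusted p = 0.154). Their median of 0.27 turned to -0.0012 under quantile normalization. In Molt-4 13 of 39 were higher and 7 lower (camera adjusted p = 0.636), and the median of 0.13 turned to -0.11. IFI6 rose from 53.1 ± 1.2 to 105 ± 3.11 FPKM in Jurkat and from 21.9 ± 0.97 to 94.5 ± 1.13 FPKM in Molt-4, while USP18 fell from 17.4 ± 0.592 to 7.1 ± 0.787 FPKM and from 10.3 ± 0.497 to 6.55 ± 0.0608 FPKM. Of the NF-kB target genes, 6 of 16 were higher in Jurkat and 3 lower (camera adjusted p = 0.218). In Molt-4 8 of 16 were higher and 3 lower (camera adjusted p = 0.209). CD83 rose from 12.9 ± 0.481 to 56 ± 1.61 FPKM in Jurkat, and BIRC3 from 4.19 ± 0.295 to 20.0 ± 0.522 FPKM in Molt-4.

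Glycolysis genes divided. In Jurkat 7 of 21 were higher and 11 lower (camera adjusted p = 0.235), with a median of -0.25 and a mean of -0.0098. In Molt-4 7 of 21 were higher and 8 lower (camera adjusted p = 0.435), and the median of 0.013 turned to -0.039 with median-of-ratios scaling. LDHA fell from 589 ± 128 to 305 ± 1.23 FPKM in Jurkat and from 676 ± 14.7 to 348 ± 6.21 FPKM in Molt-4, while the glucose transporter gene SLC2A3 rose from 2.95 ± 0.20 to 15.9 ± 1.05 FPKM and from 26.2 ± 1.56 to 63.4 ± 0.722 FPKM. The glycolysis list in Jurkat had an adjusted p of 0.0461 without untreated Jurkat replicate 3 (range 0.0461 to 0.767). Of the cholesterol biosynthesis genes, 4 of 24 were higher and 9 lower in Jurkat (camera adjusted p = 0.309). FDPS fell from 388 ± 14 to 217 ± 6.4 FPKM. That list had an adjusted p of 0.0377 without untreated Jurkat replicate 3 (range 0.0377 to 0.99).

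Of the genes of the unfolded protein and integrated stress response, 4 of 27 were higher in Jurkat and 11 lower (camera adjusted p = 0.0724). In Molt-4 3 of 27 were higher and 6 lower (3 and 2 adjusted over the list alone) (camera adjusted p = 0.516). In Jurkat the list had an adjusted p of 0.0437 without untreated Jurkat replicate 1 and 0.022 without untreated Jurkat replicate 3 (range 0.022 to 0.267). Of the replication-dependent histone genes, 2 of 17 were higher in Jurkat and 4 lower (1 and 4 adjusted over the list alone) (camera adjusted p = 0.309). This list had an adjusted p of 0.0336 under quantile normalization (range 0.0336 to 0.671). In Molt-4 8 of 17 were higher and 0 lower (camera adjusted p = 0.13), with an adjusted p of 0.0447 without untreated Molt-4 replicate 2 (range 0.00461 to 0.316), and of 0.00461 with FPKM of at least 5 in 3 libraries and 0.041 within the groups compared alone. Its median of 0.44 turned to -0.15 under quantile normalization. HIST1H2AI rose from 16.6 ± 0.917 to 108 ± 5.59 FPKM in Molt-4. Of the replication-independent and linker histone genes, 6 of 10 were higher and 0 lower in Molt-4 (camera adjusted p = 0.0589). The adjusted p of that list was 0.0266 without untreated Jurkat replicate 3, 0.0419 without treated Jurkat replicate 2 and 0.0215 without treated Jurkat replicate 3 (range 0.00264 to 0.23), and 0.0348 with no filter on low values, 0.030 with FPKM of at least 5 in 3 libraries, 0.0499 with median-of-ratios scaling, 0.0063 under quantile normalization and 0.00264 within the groups compared alone. Of the histone acetyltransferase and reader genes, 3 of 13 were higher and 7 lower in Jurkat (camera adjusted p = 0.218).

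Whether chidamide brought the lines closer was tested. Across genes, which are not independent, treated Jurkat and Molt-4 libraries correlated with r of 0.849 to 0.85. Untreated ones gave 0.874 to 0.886 (9 pairs each). By this r the lines were not closer. Genes silent in both untreated lines can raise untreated r, so it cannot show that the lines moved apart.

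Other splits of the same libraries were tested like the real groups. In Jurkat 7786 genes were called with the real split and at most 0 with another, and in Molt-4 8304 and 0. Between the untreated lines these were 9044 and at most 1. In each of these 3 comparisons 10 splits are too few for a share under 0.05, with 1 split at the real value. For genes called in the same direction in both lines, 1 of 100 splits gave as many as the real 5256, with at most 394 in another. No other split of a single line called a gene, which fixes nearly all of these counts at 0, so they show no more than a response in each line. For the difference between the lines, 3 of 100 splits gave as many as the real 4416, with 9594 in the highest other. These splits exchange treated and untreated libraries within a line, so they test whether there is any response and not whether the responses are equal.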
